A study of Drosophila melanogaster with 7 samples.

How the data were processed

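Per the labels' protocols, GFP-labelled intestinal stem cells were sorted by FACS from adult Drosophila melanogaster midguts digested with elastase, about 10000 cells per sample, and their RNA was extracted and amplified, and libraries were made by standard Illumina methods. The samples were 3 Ctrl and 4 ScOE libraries. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.10 to BDGP6 and expression was computed with Cufflinks 2.2.1. The deposited unit was FPKM, fragments scaled by transcript length and by mapped fragments, for 17481 genes, and the notes do not say whether values were scaled further between libraries. They also do not say whether reads were assigned by strand, so overlapping and antisense genes are uncertain, as are near-identical gene copies.

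FPKM does not keep read numbers, so absolute depth is unknown. The most frequent ratio between libraries among values of 0.001 to 0.1 FPKM, a measure of what one fragment was worth, put the depth of the Ctrl libraries at 0.448 to 0.603 of that of ScOE 3 and of the other ScOE libraries at 0.859 to 1.04. In the 6 libraries compared with ScOE 3 that ratio was held by 23.8% to 28.5% of the low genes compared. There were 2790 genes at 0 in every library, among them all 37 mitochondrial entries, so a 0 in the table need not mean that no RNA was present.

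The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a variance trend, two-sided, over genes with at least 1 FPKM in at least 3 of the 7 libraries, with Benjamini-Hochberg adjusted p under 0.05. Values were used as deposited, with no further scaling and no covariate. Fold changes are ScOE minus Ctrl on that log2 scale. The level of sc was also compared by an exact permutation test. The 20 gene lists, the test, the rule for named genes and all alternatives but those said below to be added later were fixed before the data were examined. The lists held enteroendocrine transcription factors, peptide hormones, secretion machinery, proneural targets, the E(spl) and Bearded family, Notch components, stem cell and enteroblast markers, enterocyte, visceral muscle, hemocyte, fat body, trachea, and neuron and glia markers, G1 and S phase, G2 and M phase, JAK/STAT, EGFR and stress ligand signalling, heat shock and oxidative stress, antimicrobial peptides, mitochondrially encoded genes and ribosomal proteins. Of 517 list entries 5 were not matched, and 17176 of the 17481 gene IDs were found in the symbol table. The 17 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with adjustment over the lists, and counts are also given adjusted over the list alone.

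Named genes were a fixed set, up to 3 rising and 3 falling members of each list with the smallest adjusted p, and the 10 largest rises and falls among called genes with groups that did not overlap and a mean of at least 5 FPKM in the higher group, 101 genes in all. Small non-coding RNA classes were passed over among the largest changes; snoRNA:Me18S-U1356c would otherwise have led the falls. Other genes named in the text were chosen after their values were seen. Coordinates are 1-based on BDGP6, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

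Alternatives were pseudocounts of 0.1, 0.5 and 5, no filter or a minimum of 5 FPKM, quantile normalization, upper quartile and trimmed-mean scaling, equal FPKM totals, no variance trend, robust moderation, library weights, a replicate block, each library left out in turn, camera with an estimated correlation, fry, and stricter thresholds. An enterocyte marker covariate, leaving out both libraries numbered 1 and leaving sc out of its gene list were added after the data were seen.

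The ScOE against Ctrl test was tested on 20 simulated tables with the real group sizes, in which 200 genes were changed and 7875 to 7904 genes were tested. The changed genes were drawn from those above about 5 FPKM in Ctrl, and noise was drawn independently for each gene. Recovery at lower levels and correlation between genes were therefore not simulated. A mean of 61.4% of 2-fold changes (53% to 68%) and 89.4% of 4-fold changes (83% to 96%) were recovered. Calls without a simulated change made up a mean of 5.64% of calls, with a range over tables from 2.61% to 10.6%, against the 5% aimed at. The number of tables was raised to 20 after a single table had given the highest of these shares.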

Results

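RNA was measured by sequencing in sorted intestinal stem cells of the adult Drosophila melanogaster midgut. The midgut epithelium is renewed by intestinal stem cells, whose daughters become absorptive enterocytes or hormone-secreting enteroendocrine cells. Per the labels, flies were adults at day 2, and about 10000 GFP-labelled cells were sorted for each sample after elastase digestion of the gut. The Ctrl group held 3 libraries from wild-type flies, and the ScOE group held 4 libraries from flies overexpressing Sc. Sc is the product of scute (sc), a basic helix-loop-helix transcription factor of the proneural family, which is known to act in the formation of enteroendocrine cells. Nothing in the labels says that the libraries came from separate cultures or animals, so p-values measure only the spread between these libraries, part of which may be technical.

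The deposited table gave FPKM for 17481 genes, and 8421 of them reached 1 FPKM in at least 3 of the 7 libraries and were tested. Summed FPKM ranged from 1925000 to 2614300 in the Ctrl libraries and from 1059300 to 1382500 in the ScOE libraries. Genes at 1 FPKM or more numbered 7791 to 8182 per Ctrl library and 8093 to 8381 per ScOE library. FPKM does not keep the number of reads, so absolute depth is unknown. Pearson correlations of log2(FPKM + 1) across tested genes, which are not independent replicates, were 0.904 to 0.954 among Ctrl libraries, 0.92 to 0.978 among ScOE libraries and 0.825 to 0.887 between the groups. The first principal component held 54.8% of the variance and separated the groups, and the second held 23.7% and set Ctrl 1 and ScOE 1 apart from Ctrl 3 and ScOE 4.

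The comparison of ScOE with Ctrl asked which RNA levels differ between the sorted cells of the 2 groups. Each library is a bulk sample of sorted cells. A change within stem cells and a change in the mix of sorted cells therefore cannot be told apart for any gene or list below. The mean FPKM of sc itself was 95.5-fold higher. Its log2 fold change, on the log2(FPKM + 1) scale, was 5.77 ± 0.40 (SE, n = 3 and 4). Among tested enteroendocrine genes, 14 of 16 in the transcription factor list, 9 of 14 peptide hormones and 20 of 23 secretion genes rose. Their adjusted p was 0.128, 0.429 and 0.206 in camera with an estimated correlation. The transcription factor list includes the overexpressed sc and the adaptor gene phyl. Of the tested cell cycle genes, 29 of 34 for G1 and S phase and 33 of 39 for G2 and M phase rose (adjusted p = 0.148 and 0.128 with an estimated correlation). In the Enhancer of split complex, which holds the best known targets of Notch signalling, 7 of 11 tested genes rose and 3 fell (adjusted p = 0.305 with an estimated correlation). At the deposited scale 12 of 17 JAK/STAT, EGFR and stress ligand genes and 80 of 86 ribosomal protein genes fell (adjusted p = 0.128 and 0.305 with an estimated correlation). Each of these lists passed with the preset correlation of camera, and none with an estimated one.

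The overexpressed gene itself, sc (FBgn0004170, BDGP6 chromosome X, 396060 to 397497, plus strand), was at 1.44 ± 0.874 FPKM in Ctrl (SD, n = 3) and 137 ± 55.2 FPKM in ScOE (SD, n = 4). The 4 ScOE libraries lay between 66.0 and 190 FPKM, and no Ctrl library was above 2.44 FPKM. The adjusted p was 8.6e-05 in limma. An exact two-sided permutation test over the 35 splits of the 7 libraries gave p = 0.0286, the smallest value it can give. The annotation places the opposite-strand gene CG32816 over both sc and its neighbour ase, and the sources used here do not say whether reads were assigned by strand. The values also do not separate transcripts of the native gene from those of a transgene. The neighbouring proneural gene ase was listed at 0 in all 3 Ctrl libraries and lay between 8.40 and 13.5 FPKM in the ScOE libraries.

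Of the 8421 tested genes, 3280 changed at an adjusted p under 0.05 in limma, 1484 of them rising and 1796 falling, so 45.2% of the calls were rises. A fold of at least 2 was reached by 786 of the rising genes and 664 of the falling genes. The 2 groups did not overlap for 3895 genes, or 46.3% of those tested, where chance gives 5.71%. The split between rises and falls depended on how libraries were scaled to each other. It was 1916 rising to 1251 falling (60.5% rising) with upper quartile scaling and 4456 to 280 (94.1% rising) with each library set to the same FPKM total. The median log2 fold change of all tested genes was -0.08 as deposited, 0.08 with upper quartile scaling and 0.68 with equal totals.

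The largest rises among genes whose groups did not overlap were those of the non-coding RNA CR44272, E(spl)m8-HLH, insb, sna, E(spl)mgamma-HLH, NPFR, ventrally-expressed-protein-D, sc, CCHa1 and Fie. CR44272 (FBgn0265299, chromosome 2R, 7992196 to 7992567) went from 4.28 ± 1.08 to 2236 ± 1109 FPKM, a log2 fold change of 8.63 ± 0.36. The gene insb rose from 0.414 ± 0.330 to 166 ± 23.9 FPKM (log2 6.90 ± 0.19). NPFR, the receptor of neuropeptide F, rose from 0.368 ± 0.235 to 89.3 ± 23.5 FPKM (log2 6.03 ± 0.22). The snail family repressor sna rose from 0.610 ± 0.296 to 121 ± 30.1 FPKM (log2 6.22 ± 0.23).

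The largest falls were those of CG17633, CR43855, CG43218, CG45061, CG10477, Jon99Fii, CG18180, CG9021, Jon99Fi and CG30283. CR43855, a non-coding RNA on chromosome 2L, fell from 152 ± 52.1 to 1.91 ± 0.0812 FPKM (log2 -5.67 ± 0.21), and CG30283 fell from 134 ± 36.9 to 5.12 ± 1.19 FPKM (log2 -4.46 ± 0.23). Several of the others rested on unequal Ctrl libraries. CG17633 was at 12.4, 1525 and 199 FPKM in Ctrl 1, 2 and 3 and at 1.09 to 1.65 FPKM in ScOE; its log2 fold change of -6.09 was -4.46 without Ctrl 2 and -7.88 without Ctrl 1. CG9021 had a log2 fold change of -4.69, which was -3.83 without Ctrl 1. The log2 fold changes of CG10477 (-5.22) and CG18180 (-4.93) were -7.30 and -6.95 without Ctrl 1, -3.43 and -3.54 without Ctrl 2, and -4.95 and -4.30 without Ctrl 3. Both calls were lost without Ctrl 2 (adjusted p = 0.0723 and 0.0959 in limma), without Ctrl 3 (0.086 and 0.0928) and without ScOE 1, 2, 3 or 4 (0.0596 to 0.0792 over both genes), and with the enterocyte marker covariate (0.0674 and 0.0517). Jon99Fi had a log2 fold change of -4.51, which was -5.56 without Ctrl 1 and -2.92 without Ctrl 2, and its call was lost without ScOE 2 (log2 -4.33, adjusted p = 0.051). Jon99Fii is described with the enterocyte markers.

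Of 16 tested members of the enteroendocrine transcription factor list 14 rose, 1 fell and 1 did not pass. Adjusted over the list alone, 15 rose and 1 fell. The list also holds phyl, which encodes an adaptor. The rising members include sc itself, whose rise was set by the design; without it, a count made after the results were seen, 13 of 15 rose and 1 fell, with a median log2 fold change of 2.46 in place of 2.84 (adjusted p = 4.99e-10 in camera, and adjusted p = 0.148 with an estimated correlation). The homeodomain factor pros, the standard marker of enteroendocrine cells, rose from 1.71 ± 0.499 to 49.7 ± 7.89 FPKM (log2 4.23 ± 0.18, adjusted p = 1.07e-05). The adaptor gene phyl rose from 0.119 ± 0.105 to 27.4 ± 3.80 FPKM (log2 4.66 ± 0.14), and the proneural factor tap rose from 0.405 ± 0.269 to 12.2 ± 2.89 FPKM (log2 3.22 ± 0.21). The member that fell was the forkhead factor fkh, from 222 ± 20.5 to 109 ± 12.9 FPKM (log2 -1.02 ± 0.14), a call that was lost with equal FPKM totals (log2 -0.15). The camera test, which compares a list with all other tested genes, gave the whole list an adjusted p of 8.34e-11 with its preset correlation and an adjusted p = 0.128 with an estimated correlation. With an estimated correlation none of the 17 tested lists passed in camera, against 10 with the preset one.

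Peptide hormones of enteroendocrine cells rose for 9 of 14 tested members, fell for 2 and did not pass for 3 (adjusted over the list alone, 10 rose and 2 fell). Their median log2 fold change was 2.34. Tachykinin (Tk) rose from a mean of 17.5 FPKM in Ctrl (9.97 to 21.9) to 262 ± 103 FPKM (log2 3.81 ± 0.40), allatostatin A (AstA) from 3.03 ± 2.76 to 154 ± 85.9 FPKM (log2 5.34 ± 0.62) and CCHa1 from 16.6 ± 9.88 to 909 ± 467 FPKM (log2 5.74 ± 0.55). AstC rose from 129 ± 154 to 1764 ± 703 FPKM, with a log2 fold change of 4.45 ± 0.82 that was 3.60 without Ctrl 1 and 5.46 without Ctrl 2. CCHa2 rose by a log2 fold change of 3.77 ± 0.92, which was 2.67 without Ctrl 1 and 4.70 without Ctrl 3, and Dh31 by 2.55 ± 0.63, which was 1.92 without Ctrl 1. NPF did not pass (249 ± 277 against 737 ± 494 FPKM, adjusted p = 0.154 in limma), but passed without Ctrl 3 (log2 3.14, adjusted p = 0.0427), with equal FPKM totals (log2 2.98, adjusted p = 0.0291), with library weights (log2 1.81, adjusted p = 0.0483) and with the enterocyte marker covariate (log2 3.34, adjusted p = 0.00278). The members that fell were ITP (79.2 ± 5.02 to 20.8 ± 2.25 FPKM, log2 -1.88 ± 0.12) and Nplp2 (log2 -2.30 ± 0.55), whose call was lost without Ctrl 2 (adjusted p = 0.0515). The list gave an adjusted p of 0.00239 in camera and an adjusted p = 0.429 with an estimated correlation. The list median was 1.52 without Ctrl 1 and 2.97 without Ctrl 3, and with equal FPKM totals the call was lost (adjusted p = 0.227).

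Genes of the regulated secretion machinery, which process peptides and release vesicles, rose for 20 of 23 tested members and fell for none, and 3 did not pass. Adjusted over the list alone, the counts were again 20 and 0. As a group they had a median log2 fold change of 2.37. The prohormone convertase amon rose from 1.65 ± 0.981 to 23.3 ± 6.23 FPKM (log2 3.23 ± 0.33), the vesicle protein nSyb from 1.12 ± 0.571 to 45.5 ± 7.95 FPKM (log2 4.48 ± 0.22) and the small GTPase Rab3 from 0.850 ± 0.503 to 27.3 ± 4.17 FPKM (log2 3.96 ± 0.22). The list gave an adjusted p of 2.5e-11 in camera and an adjusted p = 0.206 with an estimated correlation. Among 7 tested neuron and glia markers, those listed for neurons, elav, fne, futsch and brp, rose. Those listed for glia, loco, moody and nrv2, fell, with the same counts adjusted over the list alone. The listed glia markers repo, alrm and wrapper did not reach the filter, so these falls need not come from glial cells. With equal FPKM totals moody and nrv2 lost their calls. The list as a whole did not pass (adjusted p = 0.472, and 0.646 with an estimated correlation).

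**Figure D1:**
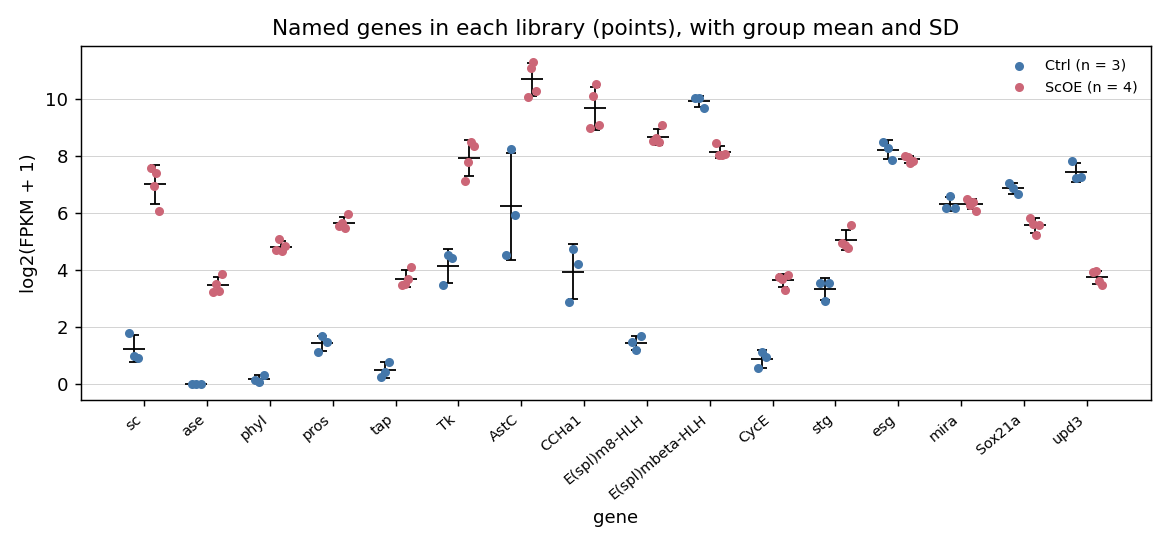
Expression of 16 named genes, as log2(FPKM + 1), in each of the 3 Ctrl and 4 ScOE libraries (points), with the group mean (horizontal bar) and SD (whiskers). The 4 ScOE libraries lie above all 3 Ctrl libraries for sc, pros, phyl, tap, Tk, AstC, CCHa1, E(spl)m8-HLH, CycE and stg and below them for E(spl)mbeta-HLH, Sox21a and upd3, while the groups overlap for esg and mira. The gene ase is listed at 0 in every Ctrl library.

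Proneural target genes rose for 6 of 13 tested members, fell for 1 and did not pass for 6 (adjusted over the list alone, 7 rose and 1 fell), with a median log2 fold change of 0.52. The ubiquitin ligase gene neur, which acts on Notch ligands, rose from 8.52 ± 0.202 to 31.2 ± 3.38 FPKM (log2 1.75 ± 0.12). The member that fell was edl, an inhibitor of the EGFR effector Pnt, from 211 ± 25.8 to 83.3 ± 8.42 FPKM (log2 -1.33 ± 0.13; -0.46 and no longer called with equal FPKM totals). Of the rising members, phyl and ase also count in the enteroendocrine transcription factor list. The proneural target list gave an adjusted p of 0.0106 in camera and an adjusted p = 0.148 with an estimated correlation.

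Genes of the Enhancer of split complex and the Bearded family moved in both directions. Of 11 tested members 7 rose, 3 fell and 1 did not pass, with the same counts adjusted over the list alone, and the median log2 fold change was 4.57. With no filter on low values 8 of 13 rose, 3 fell and the median was 0.78, so the median of this list depended on which members were tested. The basic helix-loop-helix repressor gene E(spl)m8-HLH (chromosome 3R, 26040240 to 26041008) rose from 1.74 ± 0.453 to 417 ± 87.4 FPKM (log2 7.25 ± 0.19, adjusted p = 3.05e-06), and E(spl)mgamma-HLH from 7.27 ± 0.674 to 563 ± 61.0 FPKM (log2 6.09 ± 0.13). E(spl)m4-BFM lay between 24.2 and 29.1 FPKM in ScOE and at or below 0.233 FPKM in Ctrl. In the same complex E(spl)m3-HLH fell from 1528 ± 371 to 416 ± 90.3 FPKM (log2 -1.87 ± 0.24), E(spl)mbeta-HLH from 982 ± 127 to 285 ± 42.1 FPKM (log2 -1.78 ± 0.16) and E(spl)malpha-BFM from 3905 ± 76.4 to 1238 ± 202 FPKM (log2 -1.67 ± 0.15). The directions of these 6 genes held under all 4 other scalings. The list gave an adjusted p of 0.00239 in camera, an adjusted p = 0.305 with an estimated correlation, and an adjusted p of 0.14 with equal FPKM totals.

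**Figure D2:**
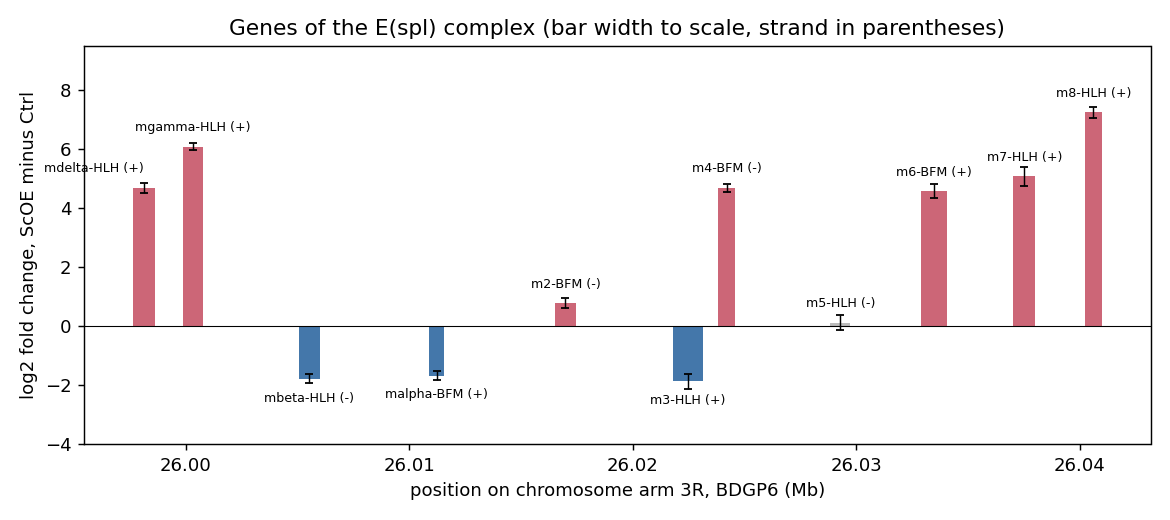
Log2 fold change (ScOE minus Ctrl, on the log2(FPKM + 1) scale) of the 11 tested genes of the Enhancer of split complex at their positions on chromosome arm 3R in megabases; bars are as wide as the genes, whiskers are SE, red bars rose, blue bars fell and grey did not pass. The falling genes E(spl)mbeta-HLH, E(spl)malpha-BFM and E(spl)m3-HLH lie among rising genes of the complex.

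Notch pathway components as a list did not pass: 6 of 21 tested members rose, 5 fell and 10 did not pass, counts that were the same adjusted over the list alone. The median log2 fold change was -0.06 while the mean was 0.13 and the camera direction was up (adjusted p = 0.472, and 0.679 with an estimated correlation). The endocytic Notch regulator spdo rose from 3.77 ± 0.835 to 27.5 ± 3.82 FPKM (log2 2.58 ± 0.17) and the ubiquitin ligase gene sina from 12.3 ± 0.742 to 25.3 ± 1.69 FPKM (log2 0.98 ± 0.11). The glycosyltransferase gene fng fell from 38.0 ± 3.82 to 6.31 ± 1.54 FPKM (log2 -2.43 ± 0.18). The receptor gene N was at 73.5 ± 27.8 and 53.1 ± 3.57 FPKM (log2 -0.40, adjusted p = 0.198; log2 0.45 with equal FPKM totals). The ligand gene Dl was at 21.6 ± 16.3 FPKM in Ctrl and 41.9 ± 9.49 FPKM in ScOE, with an adjusted p of 0.0741 in limma; without Ctrl 1, which held 40.4 FPKM, the log2 fold change was 1.68 and passed (adjusted p = 0.00236). It also passed with library weights (adjusted p = 0.00126), without both libraries numbered 1 (log2 1.73), with upper quartile scaling (log2 1.30), quantile normalization (log2 1.26) and equal FPKM totals (log2 1.95), where the median of the list was 0.69; the list median was also above 0 with upper quartile (0.09) and trimmed-mean scaling (0.05).

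Intestinal stem cell and enteroblast markers rose for 2 of 17 tested members, fell for 5 and did not pass for 10, with the same counts adjusted over the list alone (8 fell with library weights). The median log2 fold change was -0.20 and the mean 0.18 (camera adjusted p = 0.472, and 0.686 with an estimated correlation). The members that rose were sna and spdo. Sox21a fell from 117 ± 16.2 to 46.8 ± 8.13 FPKM (log2 -1.31 ± 0.17; -0.45 and no longer called with equal FPKM totals), Sox100B fell 3.04-fold from 106 ± 13.1 FPKM (log2 -1.59 ± 0.19) and the Myc gene, listed as dm, from 495 ± 21.8 to 145 ± 23.8 FPKM (log2 -1.78 ± 0.15). The marker esg was at 302 ± 66.5 and 235 ± 19.1 FPKM (log2 -0.34 ± 0.17, adjusted p = 0.16), and passed without Ctrl 3 (log2 -0.52, adjusted p = 0.0325), with library weights (log2 -0.38, adjusted p = 0.0264) and with the enterocyte marker covariate (log2 -0.48, adjusted p = 0.0356). The marker mira was at 80.2 ± 14.5 and 79.0 ± 10.2 FPKM (log2 -0.02 ± 0.16, adjusted p = 0.946), and with equal FPKM totals it passed in the other direction (log2 0.84, adjusted p = 0.0156). The list median turned above 0 with quantile normalization (0.0047) and equal FPKM totals (0.65).

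In the G1 and S phase list 29 of 34 tested members rose, 2 fell and 3 did not pass (adjusted over the list alone, 32 and 2), with a median log2 fold change of 1.00. Cyclin E (CycE) rose from 0.849 ± 0.368 to 11.5 ± 1.92 FPKM (log2 2.77 ± 0.19) and PCNA from 48.8 ± 4.40 to 161 ± 23.7 FPKM (log2 1.69 ± 0.15). The cyclin-dependent kinase inhibitor gene dap, a member of the same list, rose from 14.1 ± 5.42 to 39.7 ± 2.16 FPKM (adjusted p = 0.00318). The 2 members that fell were CycD (log2 -0.50 ± 0.13), whose call was lost without Ctrl 2 (adjusted p = 0.0552), without Ctrl 3 (adjusted p = 0.0525), without both libraries numbered 1 (adjusted p = 0.0552) and with upper quartile scaling (adjusted p = 0.0749), and whose direction turned with equal FPKM totals (log2 0.26), and its partner kinase gene Cdk4 (log2 -0.91 ± 0.21), no longer called with equal FPKM totals (log2 -0.06). In the G2 and M phase list 33 of 39 tested members rose, 2 fell and 4 did not pass (adjusted over the list alone, 35 and 2), with a median log2 fold change of 1.47. The phosphatase gene stg, which starts mitosis, rose from 9.25 ± 2.46 to 32.8 ± 9.19 FPKM (log2 1.72 ± 0.25), the kinase gene polo from 21.7 ± 1.46 to 92.8 ± 9.73 FPKM (log2 2.04 ± 0.12) and the kinesin gene pav from 3.76 ± 0.585 to 25.6 ± 2.80 FPKM (log2 2.48 ± 0.14). The members that fell were twe (log2 -0.75 ± 0.19), a Cdc25 phosphatase gene, and rap (log2 -0.47 ± 0.14), an activator gene of the anaphase-promoting complex. The call of twe was lost without Ctrl 2 (adjusted p = 0.0663) or ScOE 2 (adjusted p = 0.051) and that of rap without any 1 of Ctrl 2, Ctrl 3 and ScOE 2 to 4 (adjusted p = 0.0673 to 0.129) and under all 4 other scalings; none of the list fell with upper quartile scaling or equal FPKM totals. Both lists passed in camera (adjusted p = 2.5e-11 and 4.27e-15), with an adjusted p = 0.148 for G1 and S and an adjusted p = 0.128 for G2 and M with an estimated correlation.

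Genes of JAK/STAT, EGFR and stress signalling fell for 12 of 17 tested members and rose for none, and 5 did not pass, with the same counts adjusted over the list alone. The median log2 fold change was -1.34. The cytokine gene upd3, a ligand of the JAK/STAT pathway, fell from 174 ± 43.0 to 12.4 ± 2.18 FPKM (log2 -3.69 ± 0.20, adjusted p = 3.5e-05). Ets21C, a transcription factor gene downstream of stress signalling, fell from 527 ± 229 to 62.4 ± 8.69 FPKM (log2 -2.99 ± 0.27), and the JNK phosphatase gene puc fell from 290 ± 26.3 to 109 ± 10.1 FPKM (log2 -1.40 ± 0.12). The list gave an adjusted p of 2.71e-05 in camera and an adjusted p = 0.128 with an estimated correlation. With equal FPKM totals, where all tested genes had a median of 0.68, 8 members fell and 3 rose and the list median was -0.47, and the list still passed (adjusted p = 3.22e-09).

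Heat shock and oxidative stress genes fell for 7 of 23 tested members, rose for 2 and did not pass for 14, with the same counts adjusted over the list alone and a median log2 fold change of -0.85. With equal FPKM totals 5 rose and 2 fell, and the median was -0.06 against 0.68 for all tested genes (adjusted p = 0.000122 in camera). Hsp83 fell from 1427 ± 166 to 724 ± 82.8 FPKM (log2 -0.98 ± 0.14), a call lost with equal FPKM totals (log2 -0.11), and Gadd45 fell from 84.6 ± 23.8 to 25.1 ± 1.75 FPKM (log2 -1.68 ± 0.18). The glutathione transferase gene GstD5 rose from 4.76 ± 3.33 to 42.1 ± 5.09 FPKM (log2 3.06 ± 0.36). The adjusted p of the list was 0.0281 in camera, an adjusted p = 0.529 with an estimated correlation, and the call was lost without Ctrl 2 (adjusted p = 0.0506), without Ctrl 3 (adjusted p = 0.1), without ScOE 4 (adjusted p = 0.06), with quantile normalization (adjusted p = 0.0756) and with the enterocyte marker covariate (median -0.74, adjusted p = 0.109). The number of falling members rested on single libraries: it was 14 without Ctrl 1 (median -1.06, adjusted p = 0.000917), 12 without both libraries numbered 1 (adjusted p = 0.00146), 15 with library weights (adjusted p = 0.0128) and 4 without Ctrl 3. Of 3 tested antimicrobial peptide genes, CecC and Mtk fell and 1 did not pass (adjusted over the list alone, 3 fell); Mtk was listed at 0 in all 4 ScOE libraries and lay between 1.58 and 4.84 FPKM in Ctrl. That list did not pass (camera adjusted p = 0.0608, and 0.344 with an estimated correlation), but passed under the 4 other scalings (adjusted p up to 0.0365).

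Ribosomal protein genes fell for 80 of 86 tested members, rose for 2 and did not pass for 4 (adjusted over the list alone, 83 fell and 2 rose), with a median log2 fold change of -0.91. RpLP2 fell from 23541 ± 5033 to 8839 ± 1019 FPKM (log2 -1.40 ± 0.19) and RpS3A from 11103 ± 255 to 5908 ± 363 FPKM (log2 -0.91 ± 0.12). The members that rose, RpS15Ab (log2 1.08 ± 0.19) and RpS19b (log2 1.03 ± 0.19), are less abundant copies of other ribosomal protein genes, and reads shared between such copies make their values uncertain. The list took 33.4% to 41.2% of the summed FPKM in every library. The fall depended on the scaling. With upper quartile and trimmed-mean scaling the list median stayed at -0.74 and -0.81. Relative to the other tested genes it was -0.82 and -0.83. With equal FPKM totals 5 members fell and with quantile normalization 6, with list medians of -0.04 and -0.06. Because the list is a large part of the total, equal totals draw its own median toward 0. Quantile normalization likewise evens out the highest values, where this list lies. Relative to the other tested genes the median was -0.73 with equal FPKM totals and -0.0040 with quantile normalization, where the list no longer passed (adjusted p = 0.439) and RpLP2 and RpS3A lost their calls. The list gave an adjusted p of 4.27e-15 in camera and an adjusted p = 0.305 with an estimated correlation.

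Markers of other cell types that a sort of midgut cells could hold were measured alongside. Among 44 tested enterocyte markers 7 fell, none rose and 37 did not pass (adjusted over the list alone, 3 fell). Of all 8421 tested genes 1796 fell, a larger share. The enterocyte markers had a median log2 fold change of -0.67 and a camera adjusted p of 0.179 (0.706 with an estimated correlation). The spread between libraries was wide: the mean log2(FPKM + 1) of the 44 markers was 4.19, 6.11 and 7.40 in Ctrl 1 to 3 and 2.98, 5.52, 5.25 and 5.40 in ScOE 1 to 4. The list passed without Ctrl 1 (median -1.40, adjusted p = 0.00485), without both libraries numbered 1 (adjusted p = 0.023), with upper quartile scaling (adjusted p = 0.0225) and with equal FPKM totals (adjusted p = 3.15e-09), where its median turned to 0.11 while all tested genes had a median of 0.68. It was near 0 without Ctrl 3 (median -0.01, adjusted p = 0.964) and without ScOE 1 (median -0.13, adjusted p = 0.768), and the number of falling markers ran from 3 without ScOE 2 to 11 without Ctrl 1. The protease gene Jon99Fii fell from 374 ± 447 to 5.12 ± 0.991 FPKM (log2 -5.14 ± 0.79; -6.02 without Ctrl 1 and -4.11 without Ctrl 2), and the myosin gene Myo31DF from 96.4 ± 10.3 to 53.2 ± 7.13 FPKM (log2 -0.85 ± 0.14; 0.01 with equal FPKM totals). The enterocyte factor gene nub was at 7.33 ± 7.06 and 4.00 ± 3.69 FPKM (adjusted p = 0.597). Of 6 tested visceral muscle markers 3 fell and 3 did not pass (adjusted over the list alone, 4 fell; camera adjusted p = 0.12, and 0.4 with an estimated correlation), and that list passed without Ctrl 1 (median -0.88, adjusted p = 0.0148) and without both libraries numbered 1 (adjusted p = 0.00705); its median turned to 0.29 with equal FPKM totals. Of 5 tested hemocyte markers 2 rose, 2 fell and 1 did not pass (adjusted over the list alone, 3 rose and 2 fell; camera adjusted p = 0.465, and 0.542 with an estimated correlation). A single trachea marker was tested, btl, which fell from 3.97 ± 0.704 to 0.954 ± 0.367 FPKM (log2 -1.35 ± 0.19), and a single fat body marker, which did not pass. All 37 mitochondrial entries were listed at 0 in every library, so mitochondrially encoded genes were not tested.

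**Figure D3:**
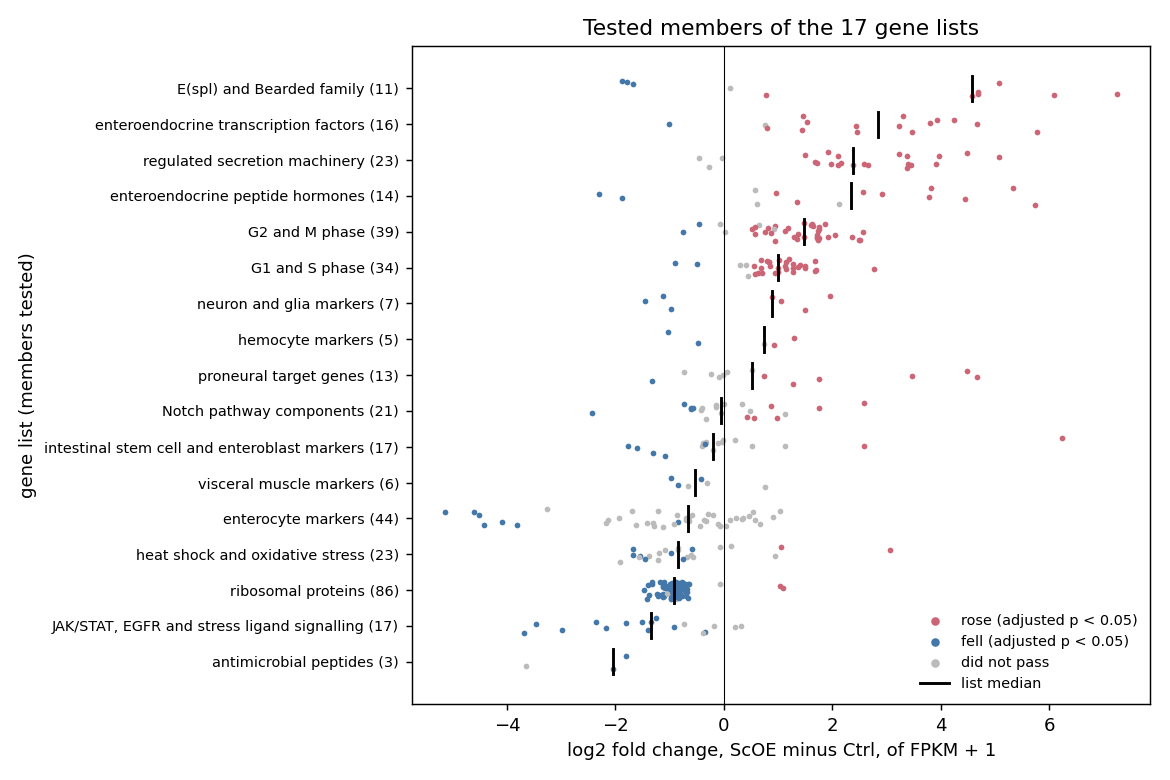
Log2 fold change (ScOE minus Ctrl, on the log2(FPKM + 1) scale) of every tested member of the 17 tested gene lists, with the list median as a black bar and the number of tested members in parentheses; red points rose, blue points fell and grey points did not pass an adjusted p of 0.05. Medians run from -2.05 for the 3 antimicrobial peptide genes to 4.57 for the E(spl) and Bearded family (0.78 with no filter on low values). With each library set to the same FPKM total the medians of the enterocyte, visceral muscle, stem cell and Notch lists turn above 0.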

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

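The tests of the scaling, the enterocyte covariates and the enterocyte median were chosen after the results were seen, and those of chance, short abundant transcripts and handling stress before.

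In 5 of 124 values tested, 1 ScOE library lay far from the other 3 by Dixon's criterion, which chance meets in about 1 of 20 groups. E(spl)mbeta-HLH was at 348 FPKM in ScOE 1 and 262 to 265 FPKM in the others. The listed glia marker nrv2 was at 54 FPKM in ScOE 4 and 48.3 to 48.6 FPKM in the others. The listed glia marker loco was at 152 FPKM in ScOE 1 and 117 to 122 FPKM in the others. The mitotic gene borr was at 109 FPKM in ScOE 4 and 92.2 to 94.3 FPKM in the others. The peptide gene Nplp2 was at 75.7 FPKM in ScOE 3 and 18.7 to 21.4 FPKM in the others.

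Of the 35 splits of the 7 libraries into 3 and 4, 1 called as many genes as the real one, the real one itself, with 3280 genes against at most 2 in any other split. The smallest p that a permutation test over 35 splits can give is 0.0286. Every other split mixes the 2 groups, which widens the spread within its groups and lowers its calls. The counts argue against chance for the number of changed genes but cannot exclude it.

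Ribosomal protein genes had a median log2 fold change of -0.91 at the deposited scale. With each library set to the same FPKM total it was -0.044, although the list stayed 0.73 below the other tested genes at that scale. The list itself held 33.4% to 41.2% of the total in every library, so equal totals draw its median toward 0. That value therefore cannot tell an effect of scaling from a fall of the list, and scaling stays open. With upper quartile and trimmed-mean scaling the median was -0.736 and -0.81. Other genes matched on transcript length and level had a median of -0.371 (middle 95% of resampled matches, -0.418 to -0.329), between no change and the list. That match was incomplete, since the matched genes were 0.912 lower in mean log2 level than the list, and the limit of 0.5 for that gap was tightened from 1 after it was seen. A loss in short, abundant transcripts therefore stays open, as does a difference between the genotypes, which was not tested apart.

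Of 44 tested enterocyte markers 7 fell, a smaller share than among all tested genes. For these 7, among them Jon99Fii and PGRP-SC2, fewer carried-over enterocytes in the ScOE libraries are a possible explanation. With the mean level of all 44 tested enterocyte markers as a covariate 5 of the 7 still fell. For these 5 that argues only against carry-over in proportion to the mean as the whole cause. Amy-d, 1 of the 5, shrank from -3.81 to -2.39. The mean includes the 7 genes and was highest in Ctrl 3 (7.40), whereas Jon65Aii, Jon99Fi and Jon99Fii were highest in Ctrl 2. Carry-over that does not follow the mean therefore stays open. The other 2 lost their calls: Jon65Ai went from -4.43 ± 1.40 to -3.82 ± 1.52 (adjusted p = 0.0826), as its fold shrank and its SE grew, and PGRP-SC2 from -4.61 ± 1.52 to -3.07 ± 1.05 (adjusted p = 0.0533), as its fold shrank, so carry-over stays open for both. With 1 library left out Jon65Ai ran from -2.62 (without Ctrl 2) to -5.93 (without Ctrl 1) and PGRP-SC2 from -3.36 to -6.58 likewise, and Jon65Ai, PGRP-SC2 and Amy-d lost their calls in 5, 6 and 6 of the 7 such fits. The 44 markers had a median log2 fold change of -0.671 and a wide spread between libraries, and a genotype difference within the sorted cells cannot be told apart from carried-over cells by that value, because the 2 sources were not measured separately.

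Of the 12 JAK/STAT, EGFR and stress genes that fell, 10 still fell with the mean level of 13 heat shock chaperones as a covariate and 11 with that of the enterocyte markers. As far as these covariates follow them, the values argue against handling stress that induces chaperones, and against carried-over enterocytes, as the whole cause. Under the 4 other scalings 11, 11, 8 and 11 of them still fell, with the lowest number, 8, at equal FPKM totals, so scaling may account for some of the members. A response to Sc overexpression stays open as a hypothesis.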

How the results depend on the processing

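The fall in the number of calls under stricter thresholds follows from their construction: 1450 genes changed at 2-fold or more (786 rising, 664 falling) and 1888 at an adjusted p under 0.01 (929 and 959). With equal FPKM totals 4456 genes rose and 280 fell. The non-coding entry CR40469 held 22.9% to 29.5% of the summed FPKM in Ctrl and 12.4% to 21.7% in ScOE. It therefore adds to the difference in totals that this scaling removes. As deposited, the median FPKM of tested genes was 14.08 to 14.14 in Ctrl and 13.65 to 13.95 in ScOE. How much of the shift in calls comes from such abundant entries was not tested. In the other alternatives that refitted all genes the number changed stayed within 1.5 times 3280 (2480 to 4840), and sc stayed past the threshold with log2 fold changes of 4.37 to 6.51. Without 1 library, 2480 to 3179 genes changed, 1148 to 1511 rose, 1325 to 1668 fell, and 9 to 12 lists passed. No list passed in camera with an estimated correlation (0 of 17, against 10), although fry, which does not compare lists with other genes, called 15. The enterocyte covariate, chosen after seeing the data, gave 3671 genes, and leaving out both libraries numbered 1, likewise, 2796.

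The labels share replicate numbers without saying what they pair. Same-numbered libraries' deviations correlated at 0.47, -0.07 and 0.33, and not every library correlated best with its own number, so the numbers were not taken as pairing; with the replicate block, where ScOE 4 has no partner, 2540 genes changed (1191 rising, 1349 falling), mira turned to 0.068, and 11 lists passed, the enterocyte list among them (median -0.847, adjusted p = 0.0113). In that fit NPF passed (adjusted p = 0.0222 in limma) and Jon99Fi did not (adjusted p = 0.0536 in limma).

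Directions turned as follows, none with a tested cause; equal totals raised the median of all tested genes to 0.68. List medians or tests turned for hemocyte (-0.065) and visceral muscle markers (0.44) with no filter, neuron and glia markers at 5 FPKM (-1.05) and equal totals (1.23), stem cell markers with quantile normalization (0.0047) and equal totals (0.65), enterocyte markers with their covariate (0.33) and equal totals (0.11), visceral muscle markers with equal totals (0.29) and Notch components with upper quartile (0.09) and trimmed-mean scaling (0.05), equal totals (0.69), library weights (0.003) and without both libraries numbered 1 (0.0086). With quantile normalization esg turned to 0.0047 and mira to 0.21, and mira to 0.16 with upper quartile and 0.088 with trimmed-mean scaling. With equal totals esg was 0.53, mira 0.84, nub 0.0071, twe 0.048, srp 0.23, Su(dx) 0.077, Tm1 0.45, N 0.45, CycD 0.26, aph-1 0.28, Myo31DF 0.0083 and rap 0.36. With the enterocyte covariate nub was 0.37. Without 1 library mira ran from -0.0906 to 0.127 and nub from -1.44 to 0.048. Of 100 named genes 67 kept direction and side of the threshold in every alternative. Unknown depth limits what can be said of genes near 0.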

Other observations

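The test of non-coding neighbours and the 16 gene families were chosen after the data were seen, and the test of the sc neighbourhood before. Genes below outside the naming rule were chosen after their values were seen.

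Hey, a basic helix-loop-helix repressor related to the E(spl) proteins and a known Notch target, rose from 0.156 ± 0.0904 to 26.5 ± 5.51 FPKM (SD, n = 3 and 4; log2 4.55 ± 0.18). The neuroblast gene dpn rose from 5.01 ± 3.25 to 118 ± 22.5 FPKM (log2 4.49 ± 0.43). The NF-kappaB gene Rel, of the immune deficiency pathway, fell from 484 ± 370 to 43.3 ± 11.2 FPKM (log2 -3.24 ± 0.47), with Ctrl 1 at 910 FPKM and Ctrl 2 and 3 at 298 and 244 FPKM. Among peptidoglycan recognition protein genes PGRP-LF fell from 82.3 ± 32.5 to 4.61 ± 2.15 FPKM (log2 -3.93 ± 0.40) and PGRP-LC fell 3.12-fold from 152 ± 9.69 FPKM (log2 -1.64 ± 0.17), while PGRP-LB rose (log2 1.16 ± 0.23). That family, with 1 of 10 tested members rising and 6 falling, did not pass (camera adjusted p = 0.0533, and adjusted p = 0.719 with an estimated correlation), but passed with quantile normalization (adjusted p = 0.0379).

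Mitochondrial ribosomal protein genes fell for 38 of 73 tested members and rose for none, with a median log2 fold change of -0.54. That was 0.459 below the median of all tested genes (camera adjusted p = 1.2e-06, and adjusted p = 0.719 with an estimated correlation). With equal FPKM totals the median of these genes turned to 0.29, which was 0.392 below that of all tested genes. Proteasome genes rose for 4 of 31 tested members and fell for none. Of all 8421 tested genes 1484 rose, a larger share. The median of the proteasome genes was 0.38 (camera adjusted p = 0.00107, and adjusted p = 0.719 with an estimated correlation). Vps genes, which act in endosomal sorting, fell for 8 of 18 tested members and rose for none. Their median was -0.41, or 0.335 below that of all tested genes (camera adjusted p = 0.0129, and adjusted p = 0.719 with an estimated correlation). With equal FPKM totals the median of the Vps genes turned to 0.389, which was 0.293 below that of all tested genes.

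Of 64 non-coding RNA entries that rose, 17 (26.6%) had a rising protein-coding gene on the same strand within 5 kb, against 47 of 320 other tested entries (14.7%). Fisher's exact test, two-sided, gave p = 0.027 with an odds ratio of 2.1. Rising entries thus lay near rising genes more often than other entries did. Neighbours on either side were counted, and the opposite strand was not compared. The test therefore cannot tell whether transcription extends from the neighbours into these entries.

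The 14 other tested genes within 100 kb of sc had a median log2 fold change of -0.0262, inside the middle 95% of windows of as many genes (-0.607 to 0.441). That argues against a rise that extends to the chromosomal neighbourhood as a set. Among single genes there ase, svr and CG32816 rose and pcl fell. CG32816 overlaps both sc and ase on the opposite strand. Whether reads were assigned by strand is not known, so its rise may come from their reads.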
